A study of Mus musculus with 2 samples.

How the data were processed

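Total RNA of mouse embryonic hearts at day 12.5 was measured in 2 libraries, which the labels call biological replicates; both carry the same strain, age and pooled sex, and form 1 group. Per the labels' protocols, RNA was extracted with a mirVana kit and the protocol cites the manual of a SMARTer low-input cDNA kit. Such kits can prime from poly(A) tails, although the assay is called total RNA. Whether ribosomal RNA was removed, and whether the libraries keep strand, are not given in the sources used here, so a gene and an overlapping antisense gene are not told apart.

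Per the file headers and the notes deposited with the samples, reads were aligned to mm10 with the GENCODE M4 annotation and quantified per gene and per transcript. The name and version of the aligner and quantifier are not given in the sources used here. The deposited expected count is an estimate of reads per gene, which need not be whole because reads shared by several genes are divided. The deposited TPM values are length-scaled shares over all listed features, spike-ins included, so a change in any abundant feature moves every other. The deposited FPKM values scale fragments by kilobase of length and by library size, and the deposited percent values give the share of each transcript in its gene. The files also deposit posterior means and SDs of the counts, used here to see where read allocation was uncertain.

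The gene tables had 69691 rows: 43346 Ensembl genes, 96 ERCC spike-ins, 1 phiX row with 0 reads and 26248 rows with numeric identifiers. Of the gene IDs 42462 matched GENCODE M21, also on the GRCm38 build, which gave names, types and coordinates; the 884 others held 0.201% of gene reads. Of the members of the gene lists, Ahsp, Snhg1, Norad and Gdf1 matched no row. Total expected counts were 34751234 in replicate 1 and 31847875 in replicate 2.

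The design, the 42 gene lists, the 33 gene pairs, the rule for naming genes and the alternatives were fixed before the data were examined. A gene was called detected at 1 TPM or more in both libraries and not detected under 0.1 TPM in both. The level of a list was the median of its members' mean TPM, set against 10000 random lists of the same size drawn from nuclear protein-coding genes. Pairs were compared as log2 ratios of TPM + 0.1 within each library. A pair was called when the sign was the same in both libraries and the mean exceeded 3 standard errors, taken from the robust SD between replicates in 20 abundance bins. The difference between libraries was the median log2 ratio of replicate 2 over replicate 1 over list members with a mean of at least 20 reads, for lists with at least 5 such members, set against 10000 random lists matched on expression. These ratios are on the log2(TPM + 0.1) scale, which understates differences of low genes. Transcript shares were computed from TPM for genes at 10 TPM or more with at least 2 transcripts at 1% or more.

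The genes named are drawn from the 15 highest protein-coding nuclear genes, up to 4 of the highest members of each list with any further detected member of a neighbouring tissue, every gene of a pair, cardiac transcription factors, the 5 largest differences between replicates each way among protein-coding genes and among list members (mean of at least 100 reads), at most 10 transcript genes, and the sex-linked lists. Ttn and the genes of the closing section that fall outside that rule were chosen after their values were seen.

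Expected counts were rounded and passed to edgeR 4.0.16 (R 4.3.3) for the common biological coefficient of variation, with TMM factors and filterByExpr; DESeq2 1.42.0 gave size factors for an alternative. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, sequence matches with blastn 2.17.0, and plots with matplotlib 3.10.9. The steps were tested on simulated counts for 43346 genes with a coefficient of variation of 5%. It was recovered as 4.96% with no gene changed and as 7.5% with 200 genes changed 2-fold, so real differences between libraries raise this estimate. A list of 20 genes shifted by 1 on the log2 scale was recovered at 0.93, and 8 of 100 unchanged lists fell outside the central 95%. Of 1000 simulated pairs, 2.1% of equal ones and 99.6% of those 2-fold apart were called. The simulated pairs carried no measurement bias that differs between genes. Alternatives covered thresholds, pseudocounts, units, scaling, filters, size factors, length and GC trends and each library alone. Intervals on read counts are exact binomial at 95% and cover counting error only, since reads copied by PCR are not independent molecules.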

Results

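RNA was sequenced from the hearts of mouse embryos of the B6NCrl strain at embryonic day 12.5, when the chambers are forming and the valves are still cushions of mesenchyme. The 2 libraries were labelled as biological replicates of 1 group, each from embryos of both sexes. Each was made from 10 ng of RNA longer than 200 nt, with synthetic ERCC spike-in RNAs added. Replicate 1 held 34751234 estimated reads and replicate 2 held 31847875, of which 33480066 and 30665239 fell on mouse genes. A count of 3 reads, the limit that a count of 0 allows, corresponded to 0.09 and 0.098 CPM of gene reads; this floor covers counting error only. With 1 group there was no contrast between conditions, and 2 libraries cannot give an exact sign test below p = 0.5, so no p-value is given. Values are the mean ± SD of the 2 libraries unless a replicate is named.

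The most abundant nuclear protein-coding transcripts were those of embryonic red cells and of the contractile apparatus. The embryonic beta globin Hbb-y (ENSMUSG00000052187.3; mm10 chromosome 7, 103851749 to 103853216) had the highest level, 25690 ± 2141 TPM (n = 2). Alpha globins followed, with Hba-a2 at 21870 ± 1551 TPM and Hba-a1 at 9887 ± 737 TPM; these copies share reads, with a posterior SD of 400 reads for each in replicate 1, against 246875 reads for Hba-a2 and 110524 for Hba-a1. Cardiac alpha actin, Actc1 (ENSMUSG00000068614.7; chromosome 2, 114047282 to 114053548), reached 9805 ± 76.9 TPM. The other members of the 15 highest were Myl2 at 6043 ± 259 TPM, Hba-x at 4971 ± 193 TPM, the natriuretic peptide gene Nppa at 4744 ± 134 TPM, Myl7 at 4678 ± 253 TPM and cardiac troponin T, Tnnt2, at 4406 ± 83.4 TPM. Below them were Atp5b at 3957 ± 3.29 TPM, Tpm1 at 3754 ± 36.1 TPM, Ppia at 3745 ± 53.6 TPM, Gapdh at 3567 ± 32.6 TPM, Ftl1 at 3361 ± 84.1 TPM and the adult beta globin Hbb-bt at 3213 ± 252 TPM. In all, 13766 genes had at least 1 TPM in both libraries, of which 12344 were nuclear protein-coding genes and 624 were long noncoding RNAs. The 8 globin genes took 2.42 ± 0.2% of all estimated reads, and the 30 genes of the sarcomere list took 5.45 ± 0.058%. As shares of TPM the order was reversed, with 6.91 ± 0.518% for the globin genes and 5.02 ± 0.0265% for the sarcomere list.

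Genes of the heart muscle cell were detected almost throughout. All 30 sarcomere and contractile genes had at least 1 TPM in both libraries, with a median of 724 TPM, above each of the 10000 random lists of protein-coding genes (percentile 100). Titin, Ttn, the giant spring of the sarcomere, stood at 496 ± 45.3 TPM. Of the 27 calcium handling and ion channel genes 25 were detected, led by phospholamban, Pln, at 481 ± 24.2 TPM, the sarcoplasmic calcium pump Atp2a2 at 329 ± 4.97 TPM, the connexin Gja1 at 270 ± 7.34 TPM and Gja5 at 122 ± 0.905 TPM. The median of that list was 21.1 TPM, at percentile 99.5 of random protein-coding lists but at 64 of random lists of detected genes. All 14 atrial genes and all 14 ventricular genes were detected, with medians of 27.7 and 80.6 TPM. The atrial list was led by Nppa, Myl7, Myl4 at 2029 ± 8.7 TPM and Pam at 314 ± 11.2 TPM, and the ventricular list by Myl2, Myh7, Myl3 and Pln. The 10 trabecular genes had a median of 53.7 TPM, with Cited1 at 801 ± 56.7 TPM. The 8 compact layer genes had a median of 75.8 TPM, led by Ankrd1 at 423 ± 8.6 TPM, Hacd1 at 193 ± 0.0354 TPM and Fhl2 at 166 ± 1.68 TPM. The 11 conduction system genes were all detected at a lower median of 8.77 TPM, led by Ntm at 41.6 ± 1.17 TPM, Smoc2 at 23.9 ± 0.163 TPM, Cpne5 at 17.1 ± 2.44 TPM and Tbx18.

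Of the 30 cardiac transcription factors 27 were detected, with a median of 16.8 TPM. That median lay at percentile 98.7 of random protein-coding lists but at 36.2 of random lists of detected genes. Nkx2-5, a homeobox factor of the heart field, was highest at 168 ± 5.9 TPM, and the zinc finger factor Gata4 followed at 159 ± 5.73 TPM. Tbx20 stood at 90.1 ± 3.76 TPM, Mef2a at 73.5 ± 5.03 TPM, Gata6 at 61.7 ± 1.2 TPM, Myocd at 59.4 ± 1.06 TPM, Irx4 at 52.4 ± 1.84 TPM and Hand1 at 52.3 ± 2.29 TPM. Between 20 and 45 TPM lay Mef2d (44.7 ± 1.65 TPM), Mef2c (39.9 ± 1.61 TPM), Hey2 (38.9 ± 2.78 TPM), Tbx5 (28.9 ± 0.474 TPM) and Gata5 (21.6 ± 2.07 TPM). Irx3 had 17.5 ± 1.56 TPM, Tbx18 16.2 ± 0.997 TPM, Nr2f2 15.8 ± 0.863 TPM, Hand2 15.8 ± 0.863 TPM, Hey1 14.8 ± 0.644 TPM, Tbx3 14.1 ± 0.389 TPM, Irx5 12.7 ± 1.17 TPM and Hopx 11.9 ± 0.0707 TPM. The lowest detected members were Srf at 8.64 ± 0.325 TPM, Shox2 at 4.65 ± 0.707 TPM, Nr2f1 at 4.6 ± 1.1 TPM, Isl1 at 4.46 ± 0.375 TPM and Tbx2 at 2.63 ± 0.0354 TPM. Tbx1 (0.315 ± 0.262 TPM) and Foxh1 (0.215 ± 0.191 TPM) lay between the detection bounds, and Mesp1, a factor of early mesoderm, was below 0.1 TPM in both libraries.

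Genes of the other cells of the heart were mostly detected as well. All 24 endocardial and endothelial genes were detected, led by Ramp2 at 196 ± 6.08 TPM, Plvap at 155 ± 9.16 TPM, Eng at 134 ± 5.24 TPM and Egfl7 at 116 ± 4.11 TPM. Their median of 33.6 TPM lay at percentile 99.9 of random protein-coding lists and at 96.3 of random lists of detected genes. All 10 coronary vessel and lymphatic genes were detected with a median of 14.6 TPM, led by Cd36 at 34.6 ± 0.212 TPM, Gja4 at 28.9 ± 2.51 TPM, Pdpn at 23.3 ± 0.099 TPM and Prox1 at 22.7 ± 1.73 TPM. The 20 valve and cushion genes were all detected (median 23.1 TPM), led by periostin, Postn, at 194 ± 1.33 TPM, Fbln2 at 171 ± 1.21 TPM, Vcan at 113 ± 6.03 TPM and Tbx20. Among 20 fibroblast and extracellular matrix genes 19 were detected (median 79.8 TPM), with Sparc at 1182 ± 33.1 TPM, Col3a1 at 569 ± 6.44 TPM, Fn1 at 352 ± 17 TPM and Col1a1 at 346 ± 25.4 TPM. The epicardial list had 14 of 16 members detected (median 17.4 TPM), led by Upk3b at 73.7 ± 0.481 TPM, Krt19 at 71.9 ± 0.467 TPM, Tcf21 at 62.2 ± 1.1 TPM and Aldh1a2 at 28.8 ± 0.537 TPM. Smooth muscle and pericyte genes were detected in 12 of 13 cases (median 22.9 TPM), led by Acta2 at 957 ± 34.4 TPM, Des at 416 ± 9.98 TPM, Cnn1 at 183 ± 1.21 TPM and Tagln at 166 ± 4.54 TPM. Of the 20 neural crest and neural genes 7 were detected (median 0.473 TPM), and Ednrb at 90.7 ± 5.08 TPM stood far above Tubb3 at 6.82 ± 0.884 TPM and Erbb3 at 6.18 ± 0.0636 TPM.

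Blood cells contributed RNA as well. All 23 matched erythroid genes were detected (median 42.4 TPM), led by the globins Hbb-y, Hba-a2, Hba-a1 and Hba-x. Of 18 macrophage and leukocyte genes 14 were detected (median 5.28 TPM), led by Lyz2 at 77.2 ± 4.84 TPM, Pf4 at 61.8 ± 9.31 TPM, C1qb at 15.5 ± 0.325 TPM and Fcer1g at 12.9 ± 0.594 TPM. Of 12 megakaryocyte and platelet genes 11 were detected (median 6.33 TPM), led by Thbs1 at 92.8 ± 3.79 TPM, Pf4, Vwf at 16.7 ± 0.976 TPM and Itga2b at 15.9 ± 3.46 TPM.

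Markers of neighbouring tissues were mostly low. Detection alone does not tell RNA of such a tissue from expression in the heart itself. In the liver list 16 of 20 genes had at least 1 TPM in replicate 1 and 8 in replicate 2. The 8 genes detected in both libraries were all lower in replicate 2: Afp, Trf at 48 ± 25.9 TPM, Apoa2, Apoa1 at 13.5 ± 9.69 TPM, Rbp4, Alb, Ttr at 2.75 ± 1.94 TPM and Ahsg at 1.53 ± 0.622 TPM. Of 17 lung and foregut genes 6 were detected, namely Id2 at 346 ± 3.02 TPM, Bmp4 at 26 ± 1.9 TPM, Irx2 at 12.6 ± 0.0283 TPM, Epcam at 2.11 ± 0.573 TPM, Irx1 at 2.05 ± 0.0354 TPM and Cldn6 at 2 ± 0.615 TPM. Irx1 and Irx2 were also members of the ventricular list, Bmp4 of the valve list and Id2 of the signalling list. In the skeletal muscle list 8 of 20 genes were detected: Tnnt1 at 445 ± 5.2 TPM, Myl1 at 412 ± 15.7 TPM, Ckm at 41.7 ± 0.318 TPM, Tnni2 at 41.4 ± 0.764 TPM, Mylpf at 12.8 ± 0.679 TPM, Tnnt3 at 6.32 ± 1.87 TPM, Actn3 at 3.46 ± 0.099 TPM and Myog at 1.37 ± 0.523 TPM. Only Nes at 27.1 ± 1.12 TPM and Fabp7 at 2.31 ± 1.22 TPM passed 1 TPM in both libraries among 16 brain genes, and only Hhex at 11 ± 0.318 TPM and Tg at 3.92 ± 0.12 TPM among 10 thymus, thyroid and parathyroid genes.

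**Figure D1:**
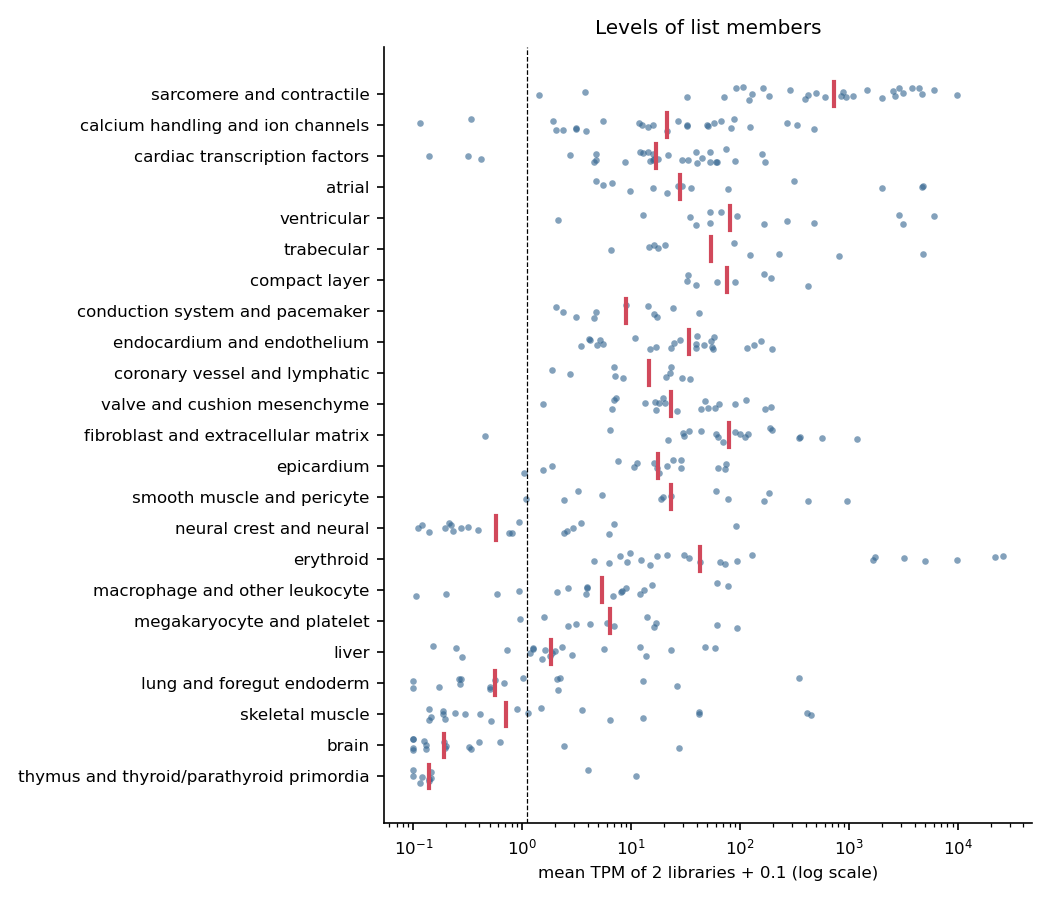
Each point is the mean TPM of 1 gene over the 2 libraries, plus 0.1, on a log axis; rows are gene lists, red bars are list medians and the dashed line marks 1 TPM. Among the 23 lists shown the sarcomere list has the highest median, 724 TPM, and the brain list has a median of 0.0925 TPM.

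Heart muscle switches between members of gene families as it matures, and 33 pairs of related genes were compared within each library. Beta myosin heavy chain, Myh7 (chromosome 14, 54970684 to 54994626), was 2.88 ± 0.285-fold above the adjacent alpha myosin gene Myh6 (chromosome 14, 54941921 to 54966927), at 3135 ± 116 against 1091 ± 67.8 TPM. The fetal troponin I gene Tnni1 (2553 ± 25 TPM) was 1.75 ± 0.0285-fold above the cardiac form Tnni3 (1460 ± 9.51 TPM). Ventricular Myl2 was 1.3 ± 0.125-fold above atrial Myl7, and Myl3 (2886 ± 87.2 TPM) was 1.42 ± 0.049-fold above Myl4. Actc1 was 25 ± 0.184-fold above skeletal Acta1 (392 ± 0.184 TPM) and 10.3 ± 0.45-fold above smooth muscle Acta2. All 33 pairs had the same sign in both libraries and differed by more than 3 standard errors, with the first gene higher in 24 and the second in 9. The standard error covers only the typical spread between replicates of genes of like abundance. It leaves out the spread of the pair itself, and errors of length or read assignment that differ between genes. Small folds, such as 1.3 for Myl2 over Myl7, are therefore less secure than this rule implies.

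Among signals and channels, Nppa was 20.8 ± 0.342-fold above Nppb (228 ± 2.69 TPM), Bmp2 (20.1 ± 1.41 TPM) was 3.17 ± 0.509-fold above Bmp10 (6.39 ± 0.58 TPM), and Gja1 was 2.21 ± 0.0765-fold above Gja5. Pln was 18.8 ± 5.4-fold above sarcolipin, Sln (26.6 ± 6.34 TPM), the other inhibitor of the calcium pump. Cacna1c (49.4 ± 2.85 TPM) was 16.3 ± 0.332-fold above Cacna1d (3.04 ± 0.113 TPM), and Cacna1h (12.5 ± 1.45 TPM) was 6.72 ± 2.35-fold above Cacna1g (1.94 ± 0.46 TPM). For 3 pairs the second gene lay below 1 TPM in mean and no fold is given: Tnnc1 (2621 ± 45.5 TPM) against Tnnc2 (0.8 ± 0.707 TPM), Ryr2 (15.7 ± 1.11 TPM) against Ryr1 (0.105 ± 0.00707 TPM) and Hcn4 (2.27 ± 0.212 TPM) against Hcn2 (0.015 ± 0.0212 TPM). Ventricular Irx4 was 3.33 ± 0.298-fold above atrial Nr2f2, Hey2 was 2.64 ± 0.303-fold above Hey1, and Hand1 was 3.32 ± 0.0365-fold above Hand2.

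In metabolism, the glucose transporter Slc2a1 (283 ± 0.686 TPM) was 12.7 ± 0.959-fold above the insulin-responsive Slc2a4 (22.3 ± 1.63 TPM), Hk1 (181 ± 6.34 TPM) was 6.33 ± 0.269-fold above Hk2 (28.6 ± 0.212 TPM) and Ldha (2342 ± 15.4 TPM) was 3.84 ± 0.036-fold above Ldhb (611 ± 1.7 TPM). Eno1 (1773 ± 23.2 TPM) was 9.13 ± 0.118-fold above Eno3 (194 ± 0.0283 TPM), Ckb (293 ± 7.77 TPM) 7.01 ± 0.133-fold above Ckm, and Pgam1 (719 ± 11.9 TPM) 1.18 ± 0.0481-fold above Pgam2 (611 ± 14.9 TPM). Muscle forms led in 2 metabolic pairs: Cpt1b (117 ± 5.57 TPM), which admits fatty acids to mitochondria, was 6.55 ± 0.346-fold above Cpt1a (17.9 ± 0.0919 TPM), and Slc25a4 (1371 ± 1.12 TPM) was 1.67 ± 0.0337-fold above Slc25a5 (821 ± 17.2 TPM). The ubiquitous cytochrome oxidase subunits were above the muscle forms, Cox6a1 over Cox6a2 by 1.99 ± 0.0471-fold, Cox7a2 over Cox7a1 by 2.67 ± 0.00294-fold and Cox8a over Cox8b by 22.3 ± 1.43-fold. All 24 glycolysis genes (median 259 TPM), all 26 fatty acid oxidation genes (median 109 TPM) and all 26 nuclear genes of oxidative phosphorylation (median 618 TPM) were detected. They were led by Gapdh and Ldha, by Fabp3 at 633 ± 20.6 TPM and Etfb at 377 ± 6.65 TPM, and by Atp5b and Cox6c at 1622 ± 21 TPM. Growth factor Igf2 (1078 ± 19.7 TPM) was 26.5 ± 0.24-fold above Igf1 (40.7 ± 0.375 TPM), and Mycn (61.5 ± 0.12 TPM) was 2.1 ± 0.183-fold above Myc (29.4 ± 2.62 TPM). Hbb-y was 7.99 ± 0.04-fold above Hbb-bt, and Hba-a1 was 1.99 ± 0.0712-fold above the embryonic Hba-x. Hba-a1 shares reads with Hba-a2, and Hbb-bt with Hbb-bs. The alpha ratio leaves out Hba-a2 (21870 ± 1551 TPM), the other adult copy, so it is not the ratio of all adult to embryonic alpha globin.

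**Figure D2:**
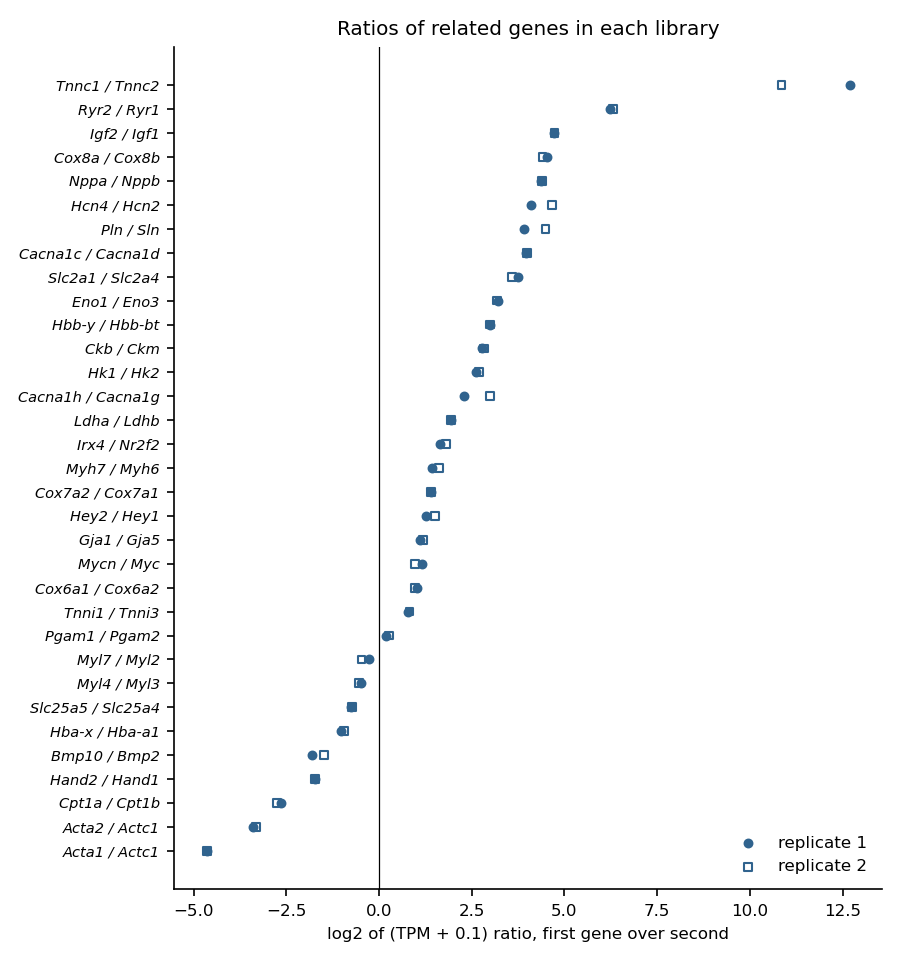
The log2 ratio of TPM + 0.1 of 33 pairs of related genes, first gene over second, with filled circles for replicate 1 and open squares for replicate 2. The ratios fall on the same side of 0 in both libraries for all 33 pairs, from -4.64 for Acta1 over Actc1 to 11.77 for Tnnc1 over Tnnc2, where Tnnc2 is near the floor.

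Dividing cells were evident in the RNA of both libraries. All 25 S phase genes were detected (median 70.3 TPM), led by Rrm2 at 229 ± 1.79 TPM, Mcm6 at 153 ± 0.728 TPM, Pcna at 142 ± 2.07 TPM and Slbp at 117 ± 1.76 TPM. All 25 genes of G2 and M phase were detected (median 69.9 TPM), led by Ube2c at 373 ± 3.94 TPM, Cdk1 at 274 ± 0.389 TPM, Birc5 at 204 ± 0.318 TPM and Cenpa at 197 ± 10 TPM. Of 14 cell cycle exit genes 13 were detected (median 24.5 TPM), with the inhibitor Cdkn1c at 792 ± 49.9 TPM, Cdkn2d at 80.3 ± 0.467 TPM, Meis1 at 64.5 ± 3.01 TPM and Cdkn1a at 41.9 ± 1.75 TPM. All 33 genes of Notch, BMP, Wnt, neuregulin and IGF signalling were detected (median 21.5 TPM), led by Igf2, Id2, Id3 at 262 ± 0.375 TPM and Igf2r at 248 ± 9.95 TPM. Among the 29 matched genes of congenital heart defects, 24 were detected (median 28.9 TPM), led by Actc1, Myh6, Flna at 184 ± 1.46 TPM and Nkx2-5.

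By class of RNA, nuclear protein-coding genes took 90.9 ± 0.0786% of estimated reads and 79.8 ± 0.28% of TPM. Mitochondrially encoded genes took 2.04 ± 0.00573% of reads, and all 15 in the list were detected, led by mt-Atp6 at 8334 ± 314 TPM, mt-Atp8 at 7420 ± 325 TPM, mt-Rnr2 at 4527 ± 44.8 TPM and mt-Cytb at 3385 ± 56.1 TPM. This order and the share are uncertain, since some mitochondrial genes, such as mt-Co3, have near-identical nuclear copies to which reads were assigned. With 6 such copies on chromosome 1 included, the share was 2.615 ± 0.00581% of reads. Long noncoding RNAs took 1.58 ± 0.0517% of reads. Among the 21 matched long noncoding genes 15 were detected (median 11.8 TPM), led by Malat1 at 5446 ± 158 TPM, H19 at 738 ± 68.3 TPM, Gas5 at 281 ± 0.495 TPM and Meg3 at 226 ± 14.4 TPM. Small and structural RNAs took 0.188 ± 0.00214% of reads and 1.77 ± 0.00175% of TPM, and 6 of 14 in the list were detected; the way RNA was primed is not given in the sources used here, so these levels and those of replication-dependent histones are not measures of cell content. The signal recognition particle RNAs Rn7s1 (6822 ± 266 TPM) and Rn7s2 (6426 ± 294 TPM) led that list, but they are near-identical and their split is uncertain; Rn7sk stood at 144 ± 3.58 TPM and Rpph1 at 41.8 ± 1.87 TPM. Of 24 replication-dependent histone genes 21 were detected (median 4.54 TPM), led by Hist1h4d at 130 ± 6.27 TPM, Hist1h2ae at 75.3 ± 6.04 TPM, Hist1h2bc at 67.9 ± 6.58 TPM and Hist1h1c at 31.5 ± 3.11 TPM. All 8 replication-independent histone genes were detected (median 233 TPM), led by H3f3a at 1320 ± 37.1 TPM, H2afz at 1057 ± 15.1 TPM, H3f3b at 604 ± 6.73 TPM and H2afv at 248 ± 0.509 TPM. All 25 ribosomal protein genes were detected (median 596 TPM), led by Rpl32 at 1139 ± 40.4 TPM, Rps29 at 1077 ± 11.4 TPM and Rps14 at 917 ± 28 TPM. Spike-ins took 3.69 ± 0.0392% of reads; 81 of 96 were counted in both libraries, and over the 63 with at least 10 reads in both, Pearson's r of log2 TPM was 0.998.

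Within genes, the leading transcript was mostly the same in both libraries. Among 5887 genes at 10 TPM or more with at least 2 transcripts, 5543 (94.2%) had the same leading transcript. Over all 5887 genes the median share of the leading transcript was 67.3%. In Tnnt2 the leading transcript (ENSMUST00000179863.3) held 65 ± 0.71% and the next (ENSMUST00000112087.4) 12.4%. Of the pyruvate kinase gene Pkm, ENSMUST00000163694.2 held 57.3 ± 0.13% and ENSMUST00000034834.11 held 42.7 ± 0.13%. The leading transcript held 50.3 ± 0.62% of Fn1 and 43.9 ± 1.66% of Postn, both matrix genes. In Ldb3, a Z-disc gene, the 2 main transcripts held 49 ± 1.84% and 45.2 ± 2.43%, and the leading transcript of Pdlim5 held 68 ± 0.87%. The leading shares were 45 ± 1.13% for Camk2d, 68.1 ± 2.28% for Mef2a, 54.1 ± 1.2% for Fxr1 and 58.8 ± 1.8% for Rbfox2. These shares are estimates from short reads over overlapping transcripts.

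The 2 libraries differed most in genes of the liver. All 16 liver genes with a mean of at least 20 reads were lower in replicate 2, with a median log2 ratio of -2.15, below each of the 10000 random lists matched on expression (percentile 0). Alpha-fetoprotein, Afp (chromosome 5, 90490737 to 90508907), had 99.3 TPM in replicate 1 and 18.2 TPM in replicate 2, and albumin, Alb, had 9.23 and 1.85 TPM. Apoa2 (log2 ratio -2.11), Rbp4 (-2.07) and Apob (-1.71) followed among list members with a mean of at least 100 reads. Over all nuclear protein-coding genes with a mean of at least 100 reads, those furthest below in replicate 2 were Serpina6 (-3.11), Itih2 (-2.85), Serpinf2 (-2.75), Ambp (-2.75) and Gabrp (-2.50). Erythroid genes were lower in replicate 2 for all 23 members, by a smaller median of -0.17.

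Platelet genes were higher in replicate 2 for 11 of 12 members (median log2 ratio 0.51, percentile 100), with Gp5 at 0.79, Gp1bb at 0.62 and Ppbp at 0.62. Myh11, a smooth muscle myosin, had 0.58 and 1.36 TPM (log2 ratio 1.10), and the other genes furthest above were Gm20388 (5.62), Gm14440 (1.10), Greb1 (1.08) and Tom1 (1.07). For Gm20388, Gm14440 and Tom1 the posterior SD of the read count was large, at 231, 77.2 and 175 reads in replicate 2, so their reads were not securely assigned; mt-Nd4l (2.13) had a posterior SD of 509 reads. Of the 37 lists with enough members, 14 had a median outside the central 95% of random lists. Lower in replicate 2 were the liver and erythroid lists, the atrial list (-0.10) and the conduction system list (-0.14). Higher were the platelet list, the G2 and M phase list (0.07, 23 of 25 members), the trabecular (0.09), endocardial (0.08) and ventricular (0.06) lists, and the sarcomere (0.04), transcription factor (0.07), valve (0.07), signalling (0.07) and immediate early (0.09) lists. Once length and GC trends were removed, 8 of the 14 stayed outside the range; the conduction, sarcomere, transcription factor, ventricular, valve and signalling lists fell inside it. Random lists ignore that genes of a list vary together, and all of these medians except those of the liver and platelet lists were under 0.2 on the log2 scale.

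**Figure D3:**
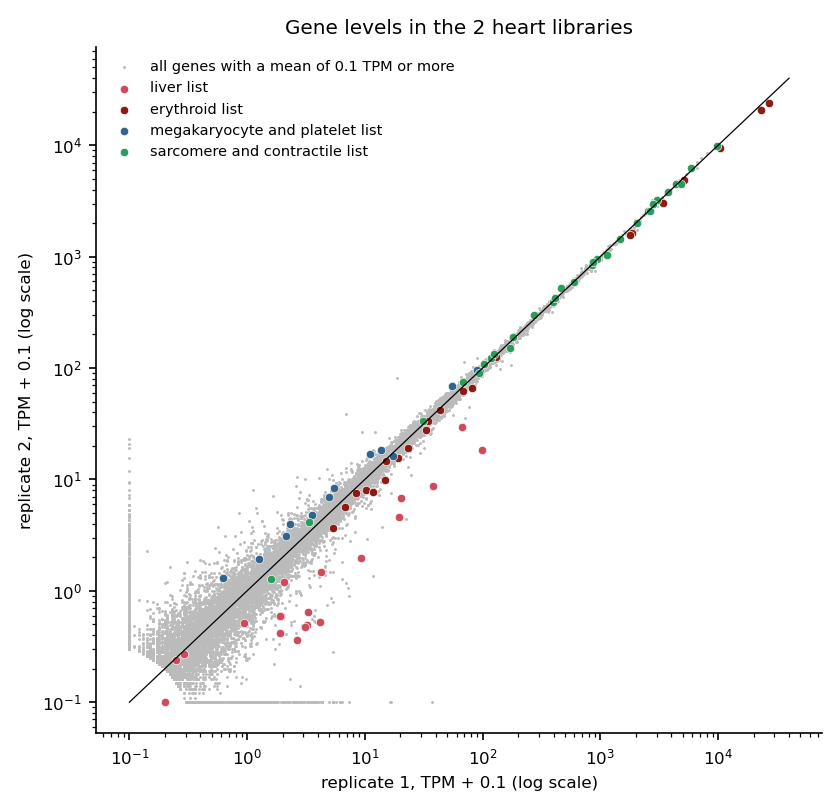
Each grey point is a gene with a mean of 0.1 TPM or more, by TPM + 0.1 in replicate 1 and replicate 2 on log axes; colours mark 4 lists and the line marks equal levels. Liver genes such as Afp (99.3 and 18.2 TPM) lie below the line, while sarcomere genes lie along it.

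**Figure D4:**
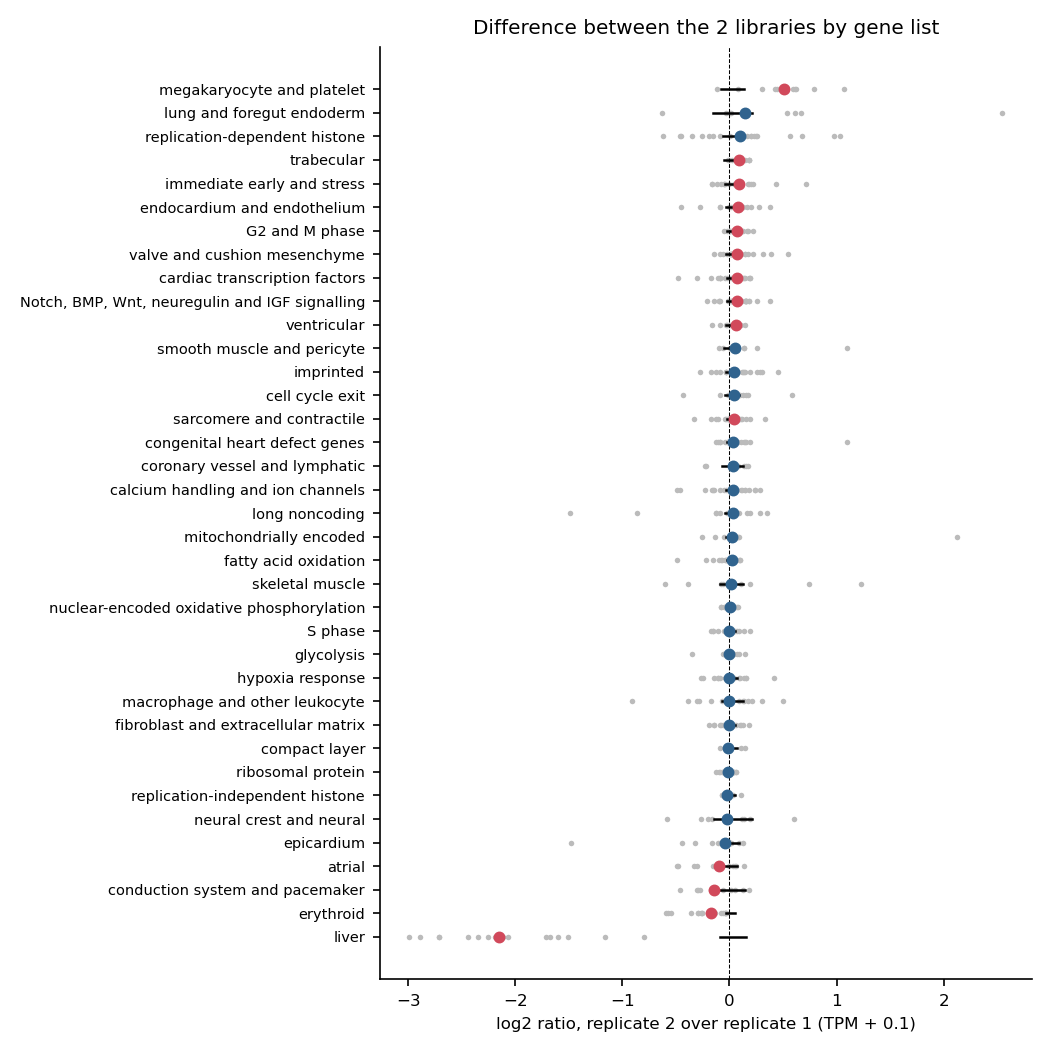
For each of 37 lists, grey points are members, the large point is the median log2 ratio of replicate 2 over replicate 1, and the black bar is the central 95% of 10000 matched random lists. The 14 red medians lie outside the bar, from -2.15 for liver to 0.51 for megakaryocyte and platelet.

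Apart from such groups, the levels of most genes were close. Across 14800 genes at 1 TPM in either library, Pearson's r of log2(TPM + 0.1) was 0.957 and Spearman's rho was 0.99; genes are not independent replicates, and r was 0.991 over genes with a mean of 20 reads. The robust SD between replicates was 0.72 on the log2 scale in the lowest abundance bin, 0.09 in a middle bin (median 15.8 TPM) and 0.04 in the highest. The levels of 570 genes (3.85%) were over 2-fold apart, and the median log2 ratio was 0.02. The common biological coefficient of variation from edgeR was 4.45%. A chi-square of the read counts over 15154 genes came to 4.6 per degree of freedom, more than read sampling alone would give; this does not show that the libraries come from different embryos.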

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

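Nothing in this part was tested, and its counts were looked at only after the files had been read. The rows with numeric identifiers, which no comparison used, held 41 reads in replicate 1 and 38 in replicate 2, above the 3 reads that a count of 0 allows. They were spread over 6 of 26248 rows, and 26238 of these rows describe features shorter than 200 nt (median 73 nt). The identifiers were not matched to names here. With 1 group of 2 libraries, neither a single sample apart from its group nor a difference between groups could be looked for.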

How the results depend on the processing

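The alternatives here were all planned. No paired analysis was possible because the design has 1 group, and leaving out a replicate gives no value for agreement or for the difference between libraries. For transcript shares, posterior mean TPM was used in place of the isoform percentage column. Genes detected (main 13766) stayed within 1.5 times for thresholds of 0.5 to 5 TPM, each unit and each single library, but was 8485 at 10 TPM. All 33 pair directions held under every setting tried. Pearson's r across genes (main 0.957) was 0.905 with a pseudocount of 0.01 TPM and 0.987 with 1 TPM, 0.991 for genes with a mean of 20 reads, 0.991 for protein-coding genes, 0.992 for log2 CPM and 0.99 for posterior mean TPM. The liver list had 8 members detected in both libraries, with a range of 8 to 16 in single libraries. With FPKM, 1 brain gene rather than 2 was detected. The share of protein-coding genes (90.9% of reads) was 79.8% of TPM and 94.4% without spike-ins and numeric rows, by construction, and single libraries gave 90.9% to 91%. Spike-ins were 3.69% of reads and 8.09% of TPM. The same leading transcript was found in 91.1% of genes at 1 TPM and 96.7% at 50 TPM. With length and GC trends removed, 10 of 37 lists differed between libraries, 8 of them among the 14 of the main analysis, and the conduction list (-0.10) and the sarcomere, transcription factor, ventricular, valve and signalling lists fell inside the random range; the cause was not tested. The immediate early list fell inside it with a pseudocount of 1 TPM, with log2 CPM and with a mean of 100 reads, and the valve list also with log2 CPM. The liver, erythroid, platelet and atrial lists stayed outside it in all 5 alternatives. Depth limits what can be said of genes below 1 TPM.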

Other observations

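A second hepatocyte list, a yolk sac list, a second lung list and a list of blood progenitors were written after the difference between libraries was seen, before their members' values were; the test of rare lung reads, its limit of 100 reads, the comparison with random gene sets, the use of the second lung list to judge it and the weight given to split members of the yolk sac list were chosen after the values had been seen.

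Imprinted genes, which are expressed from one parental copy and often regulate growth, were detected in all 23 cases with a median of 53.4 TPM. Mest stood at 2970 ± 176 TPM, Igf2 at 1078 ± 19.7 TPM, Cdkn1c at 792 ± 49.9 TPM and the noncoding H19 at 738 ± 68.3 TPM. All 18 hypoxia response genes were detected (median 25.4 TPM), led by Mif at 1871 ± 80.7 TPM, Slc2a1 at 283 ± 0.686 TPM, Bnip3 at 253 TPM and Hif1a at 185 ± 8.52 TPM. Of 20 immediate early and stress genes 17 were detected (median 24 TPM), with the small heat shock gene Hspb1 at 793 ± 64.5 TPM, Jun at 77.6 ± 0.205 TPM, Jund at 74.5 ± 6.18 TPM and Ier2 at 53.6 ± 2.52 TPM.

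Both sexes were represented in each library. Of 7 Y-linked genes 4 were detected: Eif2s3y at 29.2 and 26.7 TPM in replicates 1 and 2, Ddx3y at 16.9 and 15.8 TPM, Uty at 9.2 and 8.86 TPM and Kdm5d at 6.29 and 6.27 TPM. Zfy1, Zfy2 and Usp9y were below 0.1 TPM in both. Xist, the RNA that silences an X chromosome in females, had 10.5 and 13.5 TPM, and its antisense gene Tsix had 3.51 and 3.95 TPM. Whether the libraries keep strand is not given, so reads of Xist and Tsix may not be told apart where they overlap.

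Liver genes were higher in replicate 1. A length or GC trend between the libraries is argued against, since the liver median stayed at -2.15 after both trends were removed. Liver tissue carried into the replicate 1 pool may be a source. A second hepatocyte list had a median of -0.67, at percentile 0.01 of random lists but between the bounds of -1 and -0.5 set beforehand. Of its 11 members compared, 8 were lower in replicate 2 and 3 were higher. Apom (-2.54), Plg (-2.51) and Hpx (-2.17) were much lower there, and F10 (0.06), Fgl1 (0.05) and Cps1 (0.54) were not. Carried-over liver tissue therefore stays open. A yolk sac endoderm list had a median of 0.025, above the bound of -0.5 set beforehand, but 3 of its 10 members (Spink1, Tmprss2 and Apoa4) lay below that bound and the median rested on 7 members, so the list was not taken to decide. No biological explanation was tested, since the design has 1 group.

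A few lung genes were higher in replicate 2. Over the whole lung and foregut list, 7 of 9 members with a mean of at least 20 reads were higher there. The median log2 ratio of 0.15 lay inside the random range, at percentile 92.2. Of those 9 members, Cdh1 (117 and 65 reads in replicates 1 and 2) and Irx1 (111 and 98) were lower in replicate 2. Foxa2 (14 and 12), below the limit of 20 reads, was lower as well. Nkx2-1, a factor of lung and thyroid, had 5 reads in replicate 1 and 49 in replicate 2, and the surfactant gene Sftpc had 0 and 14. Of the reads of the 10 lung list members with fewer than 100 reads, 72.9% lay in replicate 2 (exact 95% interval 66% to 79.1%), against 47.8% of all gene reads and 36.9% to 58.5% in the central 95% of random gene sets. The share was 65.9% without Nkx2-1 (random sets 35.9% to 59.6%), 56.1% with a limit of 200 reads (40.7% to 54.2%) and 48.4% over all 17 members (46.3% to 49.6%). The last share mainly reflects Id2, which held 9523 of 11582 reads in replicate 1 and 8715 of 10847 in replicate 2. The set of rare members holds the genes in which the difference was seen. The test, first written for the 5 members that differed most, was rewritten once their reads were known. Although the share of rare members exceeded the random sets, counting noise in few reads is therefore not excluded. Lung tissue carried into the replicate 2 pool stays open as well, since a second lung list had a median of 0.14, between the bounds of 0 and 0.5, at percentile 82.7 of random lists. No biological explanation was tested.

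The pseudogene class held 6 genes of chromosome 1 between 24612407 and 24616197 (mm10), together 1.6% of TPM, including Gm28437 at 6685 ± 148 TPM and Gm29216 at 3776 ± 2.7 TPM. A candidate explanation is that reads of mitochondrial transcripts were assigned to near-identical nuclear copies: each of the 6 matched a mitochondrial gene on the same strand, at 99.71% identity or more. Posterior SDs in replicate 1 were 32.6% of the reads of Gm28437, which is identical to mt-Co3, and 123% for Gm10925, identical to mt-Atp6. In replicate 1 the SDs were lower for Gm28438 (4.28%) and Gm29216 (0.4%), and what sets the levels of these 2 was not tested. For Gm10222 the SD was 158 of 2966 reads in replicate 1 and 509 of 2569 in replicate 2.

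The list of liver blood progenitors had 3 of 10 members detected, among them Gfi1b at 4.61 and 3.19 TPM in replicates 1 and 2. Gm42418, chosen after its values were seen, had 2731 TPM in replicate 1 and 3251 TPM in replicate 2.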
